A study of Bos taurus with 4 samples.

How the data were processed

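Neutrophils were purified from the blood of cows around calving, and RNA from 4 cows was pooled at each of 4 times relative to parturition, day -7, day 0, day 0.25 and day 1, per the labels. The pools were compared on 4 two-channel cDNA arrays. Per the labels, channel 1 and channel 2 held day 0.25 and day -7 on the first array, day 1 and day 0 on the second, day -7 and day 1 on the third, and day 0 and day 0.25 on the fourth. Each pool was therefore hybridised on 2 arrays, once in each channel, and the 4 arrays form a closed loop. The arrays are named below by channel 1 over channel 2, for example "day 0.25 over day -7". Whether a pool was the same RNA on both of its arrays, whether the same cows served every day, and which dye each channel carried are not given in the sources used here.

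The deposited values are log10 ratios, one per spot and array. Raised to base 10, 100% of them fall on multiples of 0.0001 on every array, against 3.52% to 3.99% when read as log2 ratios, so each is the log10 of a ratio rounded to 4 decimals (tolerance 2% of the last decimal). How the authors corrected background, normalised or filtered is not given in the sources used here. The column medians were 0.00139 for day 0.25 over day -7, 3e-07 for day 1 over day 0, -0.000782 for day -7 over day 1 and 8.73e-05 for day 0 over day 0.25, so the deposited values are centred near 0. The deposited ratios ran only from 0.574 to 1.53. Whether they are ratios of spot intensities or of transformed intensities is not stated, so their size cannot be read as a fold change of a transcript. Which channel is the numerator is not stated either, nor that all 4 arrays run the same way. Each ratio was taken as channel 1 over channel 2. A positive difference below therefore means a higher value in the later pool only if that holds for every array, and no difference is called higher or lower. No intensity was used here, so signal over background is unknown, and the number of arrays limits the precision.

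Values were multiplied by the log2 of 10 to give log2 ratios. The 3888 spots fall into 1296 consecutive groups of 3 that the platform annotation treats as one element, and the 3 spots of an element were averaged on each array. Each array was centred on its median element. On day 0.25 over day -7, 20 spots have no value, which left 1 element without a value there and 1295 elements tested. The platform's gene annotation gave 1 gene name to 486 elements and several to 9, while 801 elements are unnamed here. Of the 486, 485 matched the current bovine gene table (ARS-UCD2.0, used for names only) by gene ID and 1 by synonym. They stand for 444 genes, 32 of them with more than 1 element, and 443 had a tested element. A gene with several elements is given as the mean over them. No coordinates are printed, since no build is given for these arrays.

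The 3 differences against day -7 were fitted to all 4 arrays for each element with limma 3.58.1 in R 4.3.3, from the design of the loop, and the differences between later days were taken from the same fit. A constant channel bias is orthogonal to these differences. The fit has 1 residual degree of freedom per element, the failure of the loop to close, to which limma's moderation added 10.9. Significance was set at a Benjamini-Hochberg adjusted p below 0.05 over the 1295 elements, for the moderated F test of any difference among the pools and for each pairwise difference. Errors given with a difference are the standard errors (SE) of this fit. There is 1 pool per day, so the tests compare these pools beyond array error and not the days beyond the spread between cows. There are no replicate pools. As a second error model chosen after the data were examined, each array was tested on its own with limma over the 3 spots of an element, which measures only the spread between spots of 1 array. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

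In simulated arrays with the observed spread and 200 changed elements among 1295, the fit of day 1 against day -7 recovered 16% of the changes of 0.05 on the log2 scale, 90% of those of 0.1 and 100% of those of 0.2 and 0.4, with 7 false calls. These rates do not carry over to the data, since many changed elements ease the adjusted threshold. In the data 4 elements passed for this comparison, and unnamed elements with differences of 0.117 and 0.111 did not.

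The sum of the 4 log ratios around the loop is 0 for each element, apart from channel bias and noise, when all arrays run the same way. Its SD over elements was compared with 100 shuffles of the elements within each array, and with the closure after turning the sign of 1 or 2 arrays. Its interval is a 95% percentile interval over 1000 bootstrap samples of the elements. Genes were grouped in 21 lists (functions of neutrophils, marker genes of other blood cells and of bone marrow precursors, and reference genes). For lists with at least 3 members on the array, the median difference was placed among 10000 random lists of the same size drawn from the named genes, as a description of these pools with no p-value.

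The lists, the tests and the rule for naming genes were fixed before the data were examined. For each comparison against day -7 the rule takes, among genes with 1 name, the 10 with the largest positive and the 10 with the largest negative difference, those past the threshold first, and for the comparisons between later days 5 of each. It adds members of the lists, and ribosomal proteins are counted but not ranked. Genes that did not pass are given as values, apart from 2 list members not reported here. The alternatives fixed in advance were no centring, arrays scaled to equal spread, the median of the 3 spots, each spot on its own, robust moderation, a filter on the spread between spots, a minimum of 3 arrays, the spread over spots with a channel term, a 1.5-fold minimum, an unadjusted p, each array left out, the direct array only, and turned signs for the closure. Chosen after the data were examined were running medians over 9, 27, 51 and 81 elements in the order of the identifiers, subtracted from each array, weights by the inverse variance of each array, and the fits with turned signs.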

Results

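Blood neutrophils, the phagocytes that make up the first cellular defence of the udder and uterus, were sampled from parturient cows a week before calving, at calving, 0.25 days after it and 1 day after it. One RNA pool of 4 cows represents each of these 4 times, and 4 two-channel cDNA arrays join the pools in a loop. Of the 1296 elements, 486 carry the name of 1 gene, among them genes of the cytoskeleton, antigen presentation, NF-kB signalling, translation and protein phosphorylation. No gene of the lists for granule proteins, T and NK cells, monocytes, eosinophils and basophils, or platelets and erythroid cells was among the named elements, so the purity of the preparations could be followed through very few genes. The values were narrow. The SD over elements was 0.046 on the log2 scale for day 0.25 over day -7, 0.018 for day 1 over day 0, 0.032 for day -7 over day 1 and 0.015 for day 0 over day 0.25. The median SD between the 3 spots of an element was 0.024, 0.012, 0.0087 and 0.0089 in the same order, and differences between the spots of an element made up 72.7%, 70.8%, 41.8% and 73.2% of the variance of all spots.

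Around the closed loop the 4 log ratios of an element sum to 0 when the arrays run the same way and channel bias and noise are absent. The sum had an SD of 0.061 over 1295 elements (95% bootstrap interval 0.058 to 0.064), within the 0.059 to 0.063 spanned by 100 shuffles in which the elements of each array were unrelated. RANGAP1, which activates the GTPase of the nuclear import protein RAN, showed how the loop stayed open. Its ratios were -0.065 for day 0.25 over day -7, then 0.14, 0.14 and 0.07 for day 1 over day 0, day -7 over day 1 and day 0 over day 0.25. HCFC1, a transcriptional co-regulator, had -0.082, 0.08, 0.12 and 0.033 in the same order. Across elements the last 3 arrays correlated positively with one another (Spearman 0.27 to 0.31), while each correlated slightly negatively with day 0.25 over day -7 (-0.096 to -0.031). With the arrays scaled to an SD of 1 the sum had an SD of 2.26, above the 1.91 to 2.09 of the shuffles, and the lowest of the 8 sign combinations gave 1.75, with day 0 over day 0.25 turned. No combination of signs closed the loop, so the direction of the ratios could not be settled from the data.

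**Figure D1:**
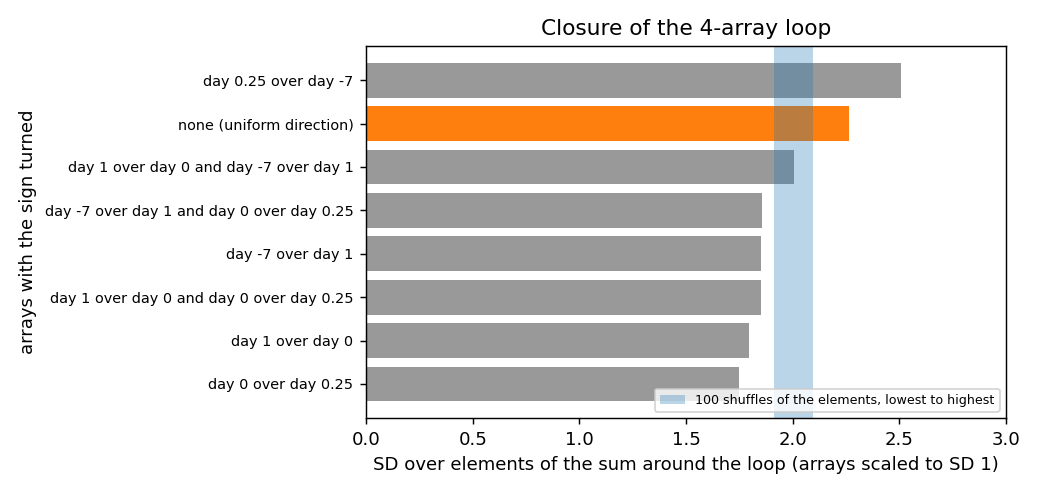
The horizontal bars give the SD over 1295 elements of the sum of the 4 log ratios around the loop, each array scaled to an SD of 1, for each combination of turned array signs, and the shaded band the range of 100 shuffles (1.91 to 2.09). The uniform direction (orange) stood at 2.26, and the combinations ran from 1.75 to 2.51.

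The F test asked which elements differed among the 4 pools in any way. LUC7L3, a splicing factor related to the U1 particle (adjusted p = 0.0361), and CPT2, a carnitine palmitoyltransferase needed for mitochondrial fatty acid oxidation (adjusted p = 0.0429), were the 2 named genes among 7 elements past the threshold. The other 5 were unnamed and stood close together in the element list. At an unadjusted p below 0.05 there were 93 elements, against 64.8 if p-values were uniform. That number is no calibrated chance level here. The fit takes the error as equal on all arrays, while their SD over elements ran from 0.015 to 0.046. Shuffling the elements within each array gave at least 7 past the threshold in 18 of 100 draws. The count was 0 without centring and with the arrays scaled to equal spread. With the median of the 3 spots in place of the mean, neither LUC7L3 (adjusted p = 0.329) nor CPT2 (adjusted p = 0.824) passed.

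The comparison of day 0.25 with day -7, the time shortly after calving against a week before it, had 26 elements past the threshold in this fit (12 positive and 14 negative), and 0 with the arrays weighted by inverse variance. Shuffled arrays gave at least as many in 19 of 100 draws. On the positive side the 1 named gene was GATD1, which encodes a protein with a glutamine amidotransferase-like domain, at 0.21 ± 0.042 (SE, adjusted p = 0.0253). On the negative side CPT2 stood at -0.20 ± 0.030 (adjusted p = 0.0101), LUC7L3 at -0.20 ± 0.029 (adjusted p = 0.0101), ADCY7, an adenylyl cyclase of blood cells, at -0.15 ± 0.029 (adjusted p = 0.0253) and TSSC4, a factor of U5 particle assembly, at -0.14 ± 0.023 (adjusted p = 0.0101). NARF, which binds prelamin A, stood at -0.14 ± 0.026 (adjusted p = 0.0253) and SEMA4B, a transmembrane semaphorin, at -0.11 ± 0.023 (adjusted p = 0.0371). RPL6, a protein of the large ribosomal subunit, passed at 1 of its 2 elements (-0.13 ± 0.027, adjusted p = 0.0371), and its elements differed in sign, with a mean of -0.059.

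Other genes of this comparison did not pass and are given as values. On the positive side were COG1 of the Golgi tethering complex (0.13), the pro-apoptotic SIVA1 (0.096), the proliferation marker MKI67 (0.095), the LIM-domain co-regulator LMO4 (0.092), the torsin TOR1B (0.086), NDRG1 (0.065), the endosomal protein LITAF (0.062), the nucleoporin NUP214 (0.059) and the NF-kB inhibitor NFKBIE (0.055), with adjusted p from 0.0563 for COG1 to 0.49 for NUP214. These depended on the array of day 0.25 over day -7. Estimated from the other 3 arrays they were 0.0007 for COG1, -0.0071 for SIVA1, -0.026 for MKI67, 0.042 for LMO4, -0.0058 for TOR1B, -0.0066 for NDRG1, 0.037 for LITAF, -0.067 for NUP214 and -0.021 for NFKBIE. On the negative side were RANGAP1 (-0.14), HCFC1 (-0.12), the nitric oxide synthase interacting protein NOSIP (-0.11) and the SLAM-family receptor CD84 (-0.11), with adjusted p from 0.0635 for HCFC1 to 0.124 for RANGAP1. From the other 3 arrays they were -0.35, -0.24, -0.019 and -0.013 in this order. With the signs of day 1 over day 0 and day -7 over day 1 turned RANGAP1 stood at 0.0036 and HCFC1 at -0.019. With the median of the 3 spots in place of the mean, LITAF (0.11), HCFC1 (-0.14), NOSIP (-0.11) and the integrin ITGAL (-0.11) passed.

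The values of the 8 named genes depended to different degrees on the array of day 0.25 over day -7 and on single spots. The SD between the spots on that array was 0.493 for CPT2, 0.281 for LUC7L3, 0.205 for the element of RPL6 that passed, 0.193 for TSSC4, 0.144 for GATD1, 0.136 for ADCY7, 0.0709 for NARF and 0.0557 for SEMA4B. With the median of the 3 spots CPT2, LUC7L3 and TSSC4 fell to -0.064, -0.087 and -0.077 and did not pass, while the other 5 did. Estimated from the other 3 arrays, with no test, the difference was 0.0027 for GATD1, -0.079 for CPT2, -0.094 for LUC7L3, -0.034 for ADCY7, -0.052 for NARF, -0.073 for SEMA4B and -0.11 for TSSC4. For RPL6 it was -0.023 as the mean over its elements, not for the element that passed alone. None of the 8 passed without centring, with the arrays scaled or after a running median over 27 elements was subtracted, although each kept its sign there. The differences changed little without centring (0.217 for GATD1, -0.201 for CPT2, -0.2 for LUC7L3), where the prior degrees of freedom fell from 10.9 to 4.61.

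**Figure D2:**
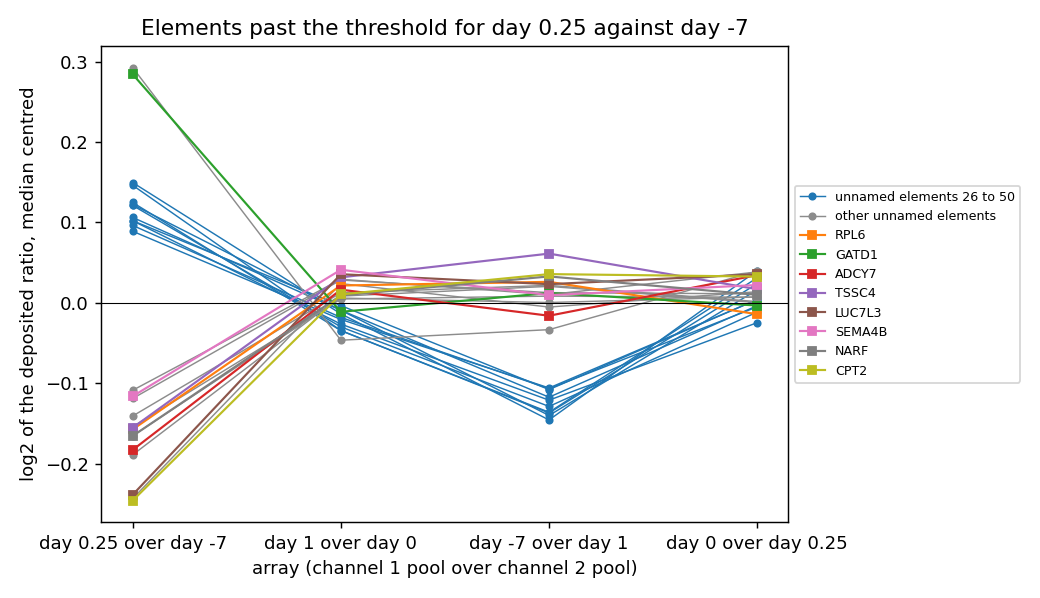
Each line joins the median-centred log2 ratios of 1 element on the 4 arrays, for the 26 elements past the threshold for day 0.25 against day -7 (squares, 8 elements with a gene name, and circles, unnamed elements). The arrays stand in the order day 0.25 over day -7, day 1 over day 0, day -7 over day 1 and day 0 over day 0.25, which is not the order around the loop. GATD1 stood at 0.28 on day 0.25 over day -7 and at -0.011, 0.012 and -0.0035 on the others, while 10 unnamed elements (blue) lay between 0.089 and 0.15 on that array and between -0.15 and -0.11 on day -7 over day 1.

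The comparison of day 0 with day -7, calving against a week before it, has no direct array. No named gene passed the threshold. The largest positive values were those of GATD1 (0.14 ± 0.048), COG1 (0.079), LMO4 (0.065), the membrane protein TMEM229B (0.061), MKI67 (0.06), SIVA1 (0.056), the triglyceride synthesis enzyme DGAT1 (0.052), TOR1B (0.049), the translocon protein TRAM1 (0.049) and the heparan sulfate sulfotransferase HS6ST1 (0.047). The largest negative values were those of RANGAP1 (-0.14 ± 0.049), LUC7L3 (-0.13), CPT2 (-0.13), HCFC1 (-0.13), TSSC4 (-0.12), NARF (-0.099), the leukocyte tetraspanin CD37 (-0.081), the mitochondrial carrier SLC25A25 (-0.081), the pseudokinase PTK7 (-0.077) and the inflammatory caspase CASP4 (-0.076). This order holds for arrays that all run the same way, and with the sign of day 1 over day 0 turned RANGAP1 stood at -0.0012 and HCFC1 at -0.046. Without the array of day 0.25 over day -7 GATD1 stood at -0.00082 and COG1 at -0.0083, and 15 of the 20 genes kept their sign. The adjusted p of these genes ran from 0.141 for TSSC4 to 0.993 for TOR1B and HS6ST1. Past the threshold were 4 unnamed elements, numbers 27, 40, 46 and 47 of the list, with positive differences of 0.14 to 0.17, singled out here after their values were seen. Shuffled arrays gave at least 4 in 13 of 100 draws. At an unadjusted p below 0.05 there were 78 elements (64.8 if p-values were uniform). Without centring or with the arrays scaled the count was 0.

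The comparison of day 1 with day -7 likewise had no named gene past the threshold. On the positive side stood GATD1 (0.058 ± 0.042), FIBP, a binding partner of acidic fibroblast growth factor (0.047), the NF-kB subunit NFKB1 (0.045), TMEM229B (0.043), the endocytic adaptor EPS15L1 (0.043), the splicing regulator TRA2A (0.04), TRAM1 (0.039), the JNK-activating kinase MAP2K7 (0.039), COG1 (0.037) and the actin-binding COTL1 (0.036). On the negative side stood HCFC1 (-0.085 ± 0.029), HSD17B4 of peroxisomal fatty acid oxidation (-0.084), CPT2 (-0.078), TSSC4 (-0.073), RANGAP1 (-0.072), the proteasomal ubiquitin receptor ADRM1 (-0.064), NARF (-0.061), LUC7L3 (-0.059), the rRNA methyltransferase METTL5 (-0.059) and PTK7 (-0.051). The lowest adjusted p among them was 0.347, for TSSC4. On the direct array GATD1 and COG1 had the opposite sign (-0.012 and -0.0066), and without it 15 of these 20 genes kept their sign. With the sign of day -7 over day 1 turned 5 did. The same 4 unnamed elements as for day 0 passed, at 0.13 to 0.15, and they passed for day 0.25 too. The pool of day -7 enters all 3 comparisons, so such an overlap arises in part from the shared pool. Shuffled arrays gave at least 4 in 16 of 100 draws. At an unadjusted p below 0.05 there were 73 elements, and the count past the threshold was 0 without centring or with the arrays scaled.

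The array of day -7 over day 1 stood apart when each array was tested over the spots of its elements. On it 547 elements passed (273 positive and 274 negative, 223 named genes), against 1 on day 1 over day 0, RANGAP1 (0.14, adjusted p = 0.0197), and 0 on each of the others. The counts at an unadjusted p below 0.05 were 683 on day -7 over day 1, 254 on day 1 over day 0, 302 on day 0 over day 0.25 and 253 on day 0.25 over day -7. The largest named positive values on day -7 over day 1 were those of RANGAP1 (0.14, adjusted p = 0.0124), HCFC1 (0.12, adjusted p = 0.0124), METTL5 (0.084), ADRM1 (0.07), the glutaryl-CoA dehydrogenase GCDH (0.068), the mitochondrial channel VDAC3 (0.065), RGMB (0.062), CD2BP2 (0.062), TSSC4 (0.061) and the ceramide synthase CERS4 (0.06). The largest negative values were those of NFKB1 (-0.093, adjusted p = 0.0357), the respiratory complex I assembly factor NDUFAF3 (-0.061), the lysosomal LAPTM5 (-0.055), MIDN (-0.049), GAPDH (-0.048), HNRNPDL (-0.047), EPS15L1 (-0.046), DAZAP2 (-0.045), FIBP (-0.042) and the nucleolar NOP53 (-0.04). After a running median over 27 elements was subtracted 317 elements passed, 255 of them the same, and METTL5 and NOP53 no longer did. These 2 lists were ranked after the array's values were seen.

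**Figure D3:**
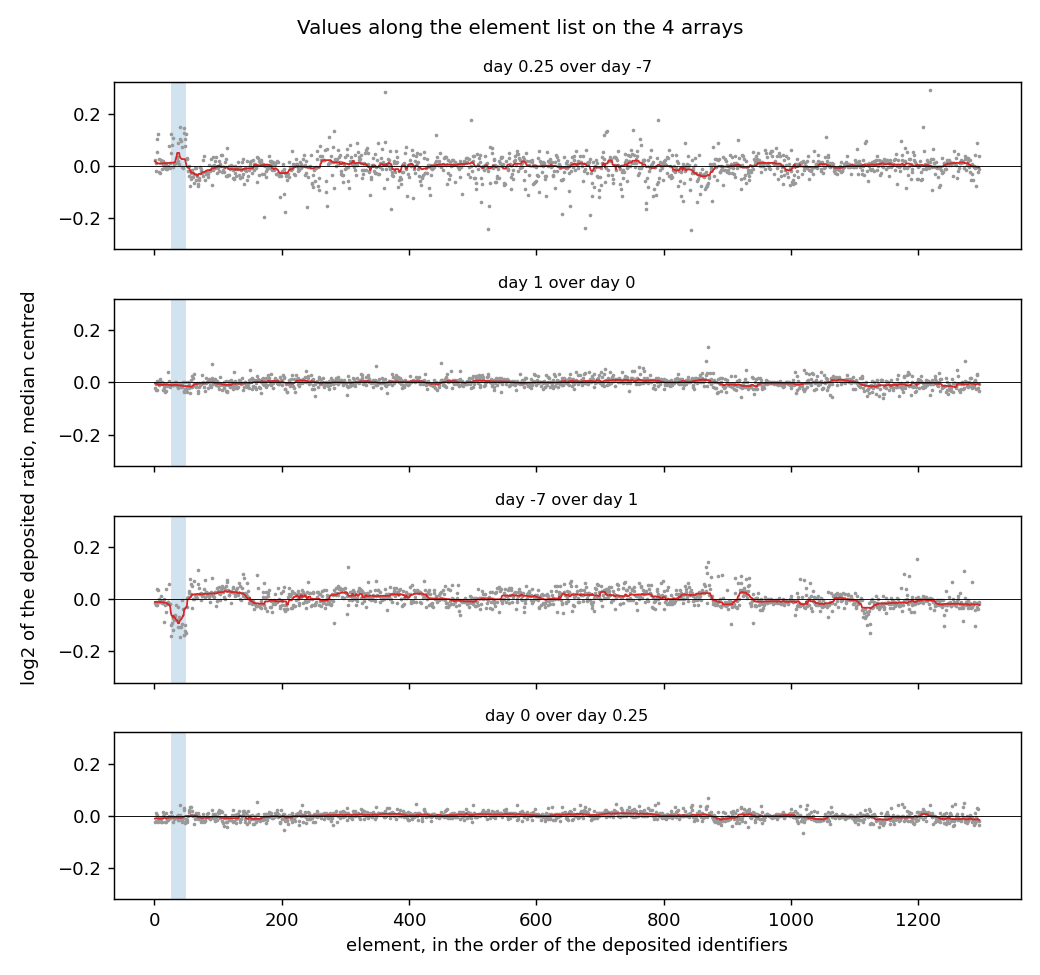
Each panel gives the median-centred log2 ratios of 1 array along the order of the identifiers (grey, elements; red, running median over 27 elements; shaded, elements 26 to 50). The running median was chosen after the data were examined.

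Between the later pools no element passed in any comparison of the loop fit as reported here. For day 0.25 against day 0 the values were 0.074 for GATD1, 0.053 for COG1, 0.041 for the Fanconi-associated FAAP20, 0.04 for SIVA1 and 0.037 for TOR1B, and -0.074 for CPT2, -0.072 for LUC7L3, -0.072 for ADCY7, -0.053 for NFKB1 and -0.042 for the glycolytic enzyme PFKL. With the sign of day 0 over day 0.25 turned PFKL stood at 0.0051, CPT2 at -0.026 and LUC7L3 at -0.019, and with that of day 0.25 over day -7 turned 2 of these 10 genes kept their sign. On the direct array GATD1 stood at 0.0035, COG1 at 0.009, CPT2 at -0.033 and NFKB1 at -0.0052. All 10 kept their sign with any 1 array left out. For day 1 against day 0.25 they were 0.14 for LUC7L3, 0.13 for CPT2, 0.12 for ADCY7, 0.085 for SEMA4B and 0.081 for NFKB1, and -0.16 for GATD1, -0.095 for COG1, -0.084 for MKI67, -0.067 for LMO4 and -0.067 for the peroxisomal PEX16. With the sign of day -7 over day 1 turned NFKB1 stood at -0.013 and PEX16 at -0.018, and with that of day 0.25 over day -7 turned none of these 10 genes kept its sign. Without day 0.25 over day -7 GATD1 stood at -0.015, CPT2 at 0.043, LUC7L3 at 0.071 and NFKB1 at -0.015, and 8 of these 10 genes kept their sign. For day 1 against day 0 they were 0.072 for LUC7L3, 0.066 for RANGAP1, 0.06 for the mitochondrial carrier UCP2, 0.053 for ADCY7 and 0.052 for CPT2, and -0.082 for GATD1, -0.048 for MKI67, -0.042 for COG1, -0.04 for LMO4 and -0.038 for the ubiquitin ligase UBR4. With the sign of day 1 over day 0 turned RANGAP1 stood at -0.14 and 8 of these 10 genes kept their sign, and with that of day 0.25 over day -7 turned 3 did. On the direct array GATD1 stood at -0.011, CPT2 at 0.01 and COG1 at 0.0017, while RANGAP1 stood at -0.148 without that array. With any 1 array left out 9 of these 10 genes kept their sign. The elements at an unadjusted p below 0.05 numbered 4, 42 and 6 in these comparisons, below the 64.8 of uniform p-values, which is no calibrated chance level here. With the spread taken over spots the counts past the threshold were 11, 139 and 21.

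Of the 21 gene lists, 8 had at least 3 members among the named genes, and RPL6 was the only member of a list past the threshold over all elements. Translation was the list of RPL6. Its 7 members (RPL6, RPL13A, RPL28, RPLP1, RPSA, RACK1 and PABPC1) had a median of -0.012 for day 0.25 against day -7, at percentile 32.1 of random lists, with 1 member past the threshold and 6 not. For day 0 and day 1 against day -7 the medians were -0.021 and -0.02, at percentiles 8.82 and 6.08, with no member past, and without the array of day -7 over day 1 they were -0.0097 and 0.00074. Without day 0.25 over day -7 the median for day 0.25 was -0.0234. Adjusted over the list alone 1 member passed for day 0 (adjusted p = 0.0385) and 1 for day 0.25 (adjusted p = 0.00483).

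The anti-apoptotic list held the NF-kB subunits NFKB1 and RELA and the inhibitor of apoptosis BIRC3. For day 0.25 against day -7 all 3 had negative values, -0.035, -0.071 and -0.052 in that order, with the median at percentile 3.67. No member passed over all elements, and 1 passed when adjusted over the list alone (adjusted p = 0.0283). At day 0 the median of -0.038 stood at percentile 5.11 and at day 1 the median of -0.025 at percentile 7.43, with NFKB1 positive at both (0.018 and 0.045). Without the array of day 0.25 over day -7 the median for day 0.25 was -0.015 and NFKB1 stood at 0.11. Without day -7 over day 1 the medians were -0.0779, -0.0831 and -0.0905 for day 0, day 0.25 and day 1, and NFKB1 turned negative at day 0 (-0.078) and day 1 (-0.098). CASP4, the 1 member of the pro-apoptotic list, stood at -0.10 ± 0.027 for day 0.25 against day -7 (adjusted p = 0.0758), and at -0.01 without day 0.25 over day -7.

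The kinases and phosphatases numbered 10 (GRK2, MAP2K7, MAP4K2, PPP1R15A, PPP2CA, PPP2R1A, PTPN2, PTPRCAP, PTPRF and STAT6), of which PTPRCAP is a phosphatase-associated protein and STAT6 a signal-activated transcription factor. Their medians were -0.021 for day 0, -0.0065 for day 0.25 and -0.018 for day 1 against day -7, at percentiles 5.08, 45.3 and 6.52, and none passed, whether over all elements or adjusted over the list alone. Without the array of day -7 over day 1 the medians for day 0 and day 1 were -0.0048 and 0.0024, and without day 0.25 over day -7 that for day 0.25 was -0.0311. The largest values at day 0 were -0.049 for PPP2R1A, a scaffold of protein phosphatase 2A, and 0.044 for MAP2K7.

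The inflammatory list held the interleukin 1 receptor IL1R1 (-0.03 for day 0.25 against day -7), the receptor-associated kinase IRAK4 (-0.027) and TREM1, an activating receptor of neutrophils (0.02). Its medians stood at percentiles 69.6, 19 and 89.9 for day 0, day 0.25 and day 1. Without day 0.25 over day -7 those for day 0 and day 0.25 went from 0.00067 and -0.027 to -0.0076 and -0.013. Of antigen presentation, the class II genes BOLA-DRA, BOLA-DMA and BOLA-DMB had values of -0.0037, 0.012 and -0.036 for day 0.25, and medians at percentiles 29.1, 51.2 and 47.4. Without day -7 over day 1 these medians turned positive, to 0.0147, 0.0129 and 0.0147. The cytoskeletal list held TPM3, MYH9, WIPF1 and MSN among its members, and its medians stood at percentiles 59.8, 76.8 and 79.6. Without day -7 over day 1 those for day 0.25 and day 1 turned negative, to -0.0052 and -0.0083. The transcription factors and chromatin proteins HMGB2, H3-3A, JUN and RUNX3 had a median of 0.0145 at day 1, at percentile 97, and of -0.011 and -0.013 at day 0 and day 0.25, at percentiles 40 and 35.7. Without day -7 over day 1 the median of this list at day 1 was -0.0166, and without day 0.25 over day -7 those at day 0 and day 0.25 were 0.0199 and 0.0189. None of the members of these 4 lists passed over all elements in any comparison, or adjusted over the list alone in the comparisons against day -7.

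The reference genes GAPDH, PKM and PGK1, enzymes of glycolysis often used as unchanging controls, had positive values in each comparison against day -7, at most 0.04 for PGK1 at day 0.25, but PKM at day 0 turned to -0.0037 with the arrays scaled to equal spread and each of the 3 turned negative in some comparison when 1 array was left out. Without day -7 over day 1, GAPDH at day 1 went from 0.03 to -0.023, and without day 0.25 over day -7, PGK1 at day 0.25 stood at -0.022. Their medians were 0.012, 0.0086 and 0.013 for day 0, day 0.25 and day 1, at percentiles 90.6, 82.1 and 93.1, and none passed, also adjusted over the list alone. Without day -7 over day 1 those for day 0 and day 1 were -0.0126 and -0.0111, and that for day 0.25 was 0.00049, against 0.0331 without day 0.25 over day -7. Lists with fewer than 3 members gave ITGAL of the adhesion list (-0.073 ± 0.024 for day 0.25 against day -7), CEBPB of the glucocorticoid response (0.0022), GBP1 and IFNGR2 of the interferon response (0.036 and 0.042), and NDUFAF3 and NDUFS7 of mitochondrial respiration (-0.018 and -0.017). Markers of other cells were CD79B of B cells (-0.01 for day 0.25 against day -7) and MKI67 of dividing precursors (0.095 ± 0.030). Without the array of day 0.25 over day -7 MKI67 stood at -0.026, GBP1 at -0.031, IFNGR2 at -0.012, NDUFAF3 at 0.059, NDUFS7 at -0.049, ITGAL at -0.022, CEBPB at 0.017 and CD79B at -0.029. None of these genes passed over all elements.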

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

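The running medians, the weights and the fits with turned signs were chosen after the results were seen, and the other settings were planned. The count of elements past the threshold depended on the setting for the F test and for the 3 comparisons against day -7, in both directions, while no element passed between later pools except where named here. Without centring, with the arrays scaled to equal spread, with each spot on its own, with a 1.5-fold minimum and after a running median over 27 elements, the count was 0 for the F test, day 0, day 0.25 and day 1 against day -7. The 1.5-fold minimum was bound to give 0 on this narrow scale, since the largest called difference for day 0.25 was 0.23 in log2. Robust moderation gave 4 by the F test and 14 for day 0.25. Weights by inverse variance gave 3 and 0 there, beside 5 for day 0 and 4 for day 1. The filter on the spread between spots gave 21 by the F test, 11 for day 0 and 12 for day 1, beside 32 for day 0.25. The running median over 9 elements gave 0 for day 0 and for day 1, beside 31 for day 0.25. That over 51 elements gave 15 by the F test, 47 for day 0.25 and 7 for day 1, and that over 81 elements gave 50 by the F test, 25 for day 0, 94 for day 0.25, 15 for day 1 and 6 for day 1 against day 0.25.

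With the spread taken over spots and a channel term, 363 elements passed the F test, and 201, 401 and 186 the comparisons of day 0, day 0.25 and day 1 with day -7. Between later pools 11 passed for day 0.25 against day 0, 139 for day 1 against day 0.25 and 21 for day 1 against day 0. This spread leaves out the failure of the loop to close. At an unadjusted p below 0.05 the counts were 93, 78, 157, 73, 4, 42 and 6 in the same order. The median of the 3 spots and a minimum of 3 arrays left every count within 1.5 times, and the median kept 21 of the 26 elements of day 0.25, without CPT2, LUC7L3 and TSSC4.

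The prior degrees of freedom of the moderation, which set how far an element with 1 residual degree of freedom borrows from the others, went along with some of these counts. They were 10.9 in the fit reported, 4.61 without centring, 5.7 with the arrays scaled and 4.78 after the running median over 27 elements, where no element passed, and 13.9, 17.3 and 78.3 for the windows of 9, 51 and 81 elements. With weights by inverse variance they stayed at 10.9, although the count for day 0.25 was 0 there. The cause of the changes in the counts was not tested.

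With turned signs the F test called 46 elements when day 1 over day 0 was turned and 0 in the other 6 combinations. In the first case 8, 84 and 31 elements passed for day 0, day 0.25 and day 1 against day -7 and 1 for day 1 against day 0, and in the other 6 none passed in any comparison. Of the 20 genes ranked in each comparison against day -7, 1 kept its sign in all combinations for day 0, and none did for day 0.25 or day 1. The SD of the loop's closure moved from 0.0614 to 0.0561 (day 1 over day 0 turned), 0.0652 (day 1 over day 0 and day -7 over day 1), 0.0553 (day 0 over day 0.25), 0.0549 (day 1 over day 0 and day 0 over day 0.25) and 0.0715 (day 0.25 over day -7), and stayed within its interval in the other 2 combinations.

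No named gene past the threshold for day 0.25 changed sign without centring, with the arrays scaled, with the median of spots, after the running median over 27 elements or with 1 array left out. Leaving out 1 array left no residual degree of freedom, so such values have no test, and those without day 0.25 over day -7 moved by more than the SE for all 8 named genes past the threshold. Of the 24 list medians, 25 values under alternatives moved by more than the SD of the members and 231 did not. The sign of 14 of the 24 list medians changed when 1 array was left out or the direct array was taken alone, and that of 3 under the other settings. No paired analysis was possible because each day has 1 pool.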

Other observations

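The tests of the run of elements 26 to 50, of the 5 calls ended by the median of spots, of the correlation of 3 arrays and of elements of the same gene were chosen after the results were seen, as were the running medians over 9, 27, 51 and 81 elements, although the bounds for 27 elements on day -7 over day 1, for the shuffling and for the median of spots were written before their counts were seen.

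The element list itself carried a pattern. No element among the first 162 or beyond the first 972 has a gene name here. Over elements 1 to 162 the arrays day 0.25 over day -7 and day -7 over day 1, which hold the day -7 pool in opposite channels, had a Spearman correlation of -0.522 across elements, and over the next 7 stretches of the list it was 0.258, 0.227, 0.0368, 0.0212, -0.23, -0.124 and -0.099. Elements are not independent replicates. Of the 26 elements past the threshold for day 0.25 against day -7, 10 lay among the 25 unnamed elements 26 to 50, with differences of 0.097 to 0.15. All 10 were positive on day 0.25 over day -7 (0.089 to 0.15), negative on day -7 over day 1 (-0.15 to -0.11) and at most 0.0347 and 0.0401 in size on day 1 over day 0 and day 0 over day 0.25. Of the 16 elsewhere, TSSC4 also opposed by at least 1.5 SD of each array. The median SD between spots on day 0.25 over day -7 was 0.0176 for the 10 and 0.136 for the 16 elsewhere.

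The 26 elements past the threshold for day 0.25 against day -7 as a number may come from wide values of single arrays alone, since shuffling the elements within each array gave at least 26 in 19 of 100 draws (highest 70). For the 10 in the run, values placed at random along the list are argued against, as 0 of 100 shuffles put 10 called elements in any stretch of 25 (highest 6), but order along the list within single arrays stays open, since shifting each array along the list did so in 2 of 100 draws (highest 12). A smooth trend along the list stays open for the run too. Its 25 elements had a Spearman correlation of -0.936 between the 2 arrays with the day -7 pool. This decides nothing because the run was picked for elements that oppose on these arrays. Neighbours in it correlated by 0.12 and 0.17 over few pairs. Subtracting a running median over 27 elements ended all 10 calls (differences 0.097 to 0.15 before, 0.032 to 0.12 after). That loss decides nothing, since no element of the whole list passed there. With 9 elements 31 elements passed for day 0.25 but 0 of the 10 (differences 0.02 to 0.08). That window is shorter than the run, so it also subtracts a level that the run's elements share, whatever its source. With 51 elements all 10 were called. Single outlying spots as the cause of all calls are argued against by the 21 of 26 that passed with the median of spots. All 10 of the run were among these. The other 5 lay among the 16 called elements outside the run, for which single spots stay open. Element 526 of these 16 has no SD between spots on day 0.25 over day -7, so the median could not test it there. Such spots may account for some of the 5, of which 3 (CPT2, LUC7L3 and TSSC4) shrank by more than 1.5 times. A real difference of the day -7 pool, a control RNA added to the pools in unequal amounts, or a bias of weak spots that follows that pool's channel all stay open and untested for the run, since its elements are unnamed here and no intensities were used.

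A single array held most of the calls over spots, 547 on day -7 over day 1. A trend along the list may carry part of them, since subtracting a running median over 27 elements left 317, between the bounds set for and against it, and windows of 9, 51 and 81 elements left 261, 370 and 402. A property of the genes was tested by the 59 pairs of elements of 32 genes, which had a Spearman correlation of 0.15 on this array, inside the central 95% of random pairings (-0.25 to 0.22). So neither explanation can be told apart from the other, because the correction removed only part of the calls and the same-gene elements are few. The same pairs correlated by -0.2 on day 0.25 over day -7, -0.079 on day 1 over day 0 and 0.11 on day 0 over day 0.25. These values also lay inside the central 95% of random pairings, so agreement between elements of the same gene was not shown on any array. No other array repeats this comparison directly, and the path over the other arrays did not reproduce it. Over 1295 elements the direct and indirect estimates had a Spearman correlation of -0.166 and the same sign in 43.9%. This was not particular to that array. For day 0.25 against day 0 the values were -0.235 and 41%, and for day 1 against day 0 -0.181 and 43.2%. For day 0.25 against day -7 they were 0.0858 and 53.1%. An indirect path carries the noise of several arrays and holds only if all arrays run the same way. A difference between the pools of day -7 and day 1 therefore stays open.

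The positive correlation of day 1 over day 0, day -7 over day 1 and day 0 over day 0.25 averaged 0.299 over the 3 pairs. A channel bias of single elements common to all 4 arrays was argued against by the array of day 0.25 over day -7. Its mean correlation with the others was -0.063, where a single correlation over as many independent elements has a standard error of 0.028. Elements are not independent here, so this error may be too small. Yet 285 elements passed for the channel term over spots, to which a bias of single arrays would also lead. A trend along the list common to the 3 arrays remains possible in part, since the mean fell to 0.195 after the running median over 27 elements. Ratios that do not all run the same way also stay open. The lowest closure of the 8 sign combinations was 1.75 against 2 for unrelated arrays, which is far from closed. It lay below the shuffles (1.91 to 2.09), but this decides nothing, as it was picked as the lowest of 8. With scaled arrays the mean square over the combinations is fixed, so values above 2 in some force values below 2 in others. No biological explanation was tested for this correlation. Per the labels, day 1 over day 0 shares day 1 with day -7 over day 1 and day 0 with day 0 over day 0.25, each in opposite channels. If all arrays run the same way, a difference of the shared pool alone would make such a pair correlate negatively.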
